A study of Xenopus laevis with 4 samples.

How the data were processed

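Total RNA was measured on 4 expression arrays, each hybridised with RNA from a different explant of Xenopus laevis embryos at stage 10, the onset of gastrulation. The explants were the animal cap (prospective ectoderm around the animal pole), the dorsal marginal zone and the ventral marginal zone (opposite sectors of the equatorial belt), and the vegetal explant (yolk-rich cells around the vegetal pole). Per the labels' protocols, the RNA was treated with DNase I and purified on a column, and biotin-labelled material was made from 100 ng of total RNA with the Ovation amplification system. Each sample was assigned to its explant by its title. There was 1 array per explant, and the labels do not say how many embryos or dissections stood behind an explant.

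The deposited values are linear intensity signals for 15611 probe sets per array. Summarisation software and scaling are not given in the sources used here. In the deposited values the mean without the lowest and highest 2% of probe sets was 500.1 on each of the 4 arrays, so the authors' values carry a scaling of each whole array to a common level, as read from the values. The number of arrays, not a depth, limits the precision. The medians of the arrays were 137 in the animal cap, 145 in the dorsal marginal zone, 158 in the vegetal explant and 146 in the ventral marginal zone. They spanned 0.21 on the log2 scale, under the limit of 0.3 set before the data were examined, so that the signals were used without further scaling.

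Signals were raised to a floor at the 20th percentile of all values (24.7) and put on the log2 scale. A probe set entered a comparison when the higher of the explants compared reached the median of all values (147). The 120 control probe sets were left out of every count, which left 15491 probe sets. A fold whose lower side lay at the floor is given as a lower bound ("at least N-fold"). The rule of size was a 2-fold difference, and percentages of probe sets are shares of those that entered the comparison.

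Probe sets were named through the platform annotation table, in which 9304 probe sets had 1 gene symbol, 195 had several and 5992 had none or were not listed. Of the identifiers behind the probe sets with 1 symbol, 9227 matched the RefSeq gene table of the assembly Xenopus_laevis_v10.1, and 2 symbols were updated from it. Probe sets with several symbols were never named. The 7531 named genes carry the suffix .L or .S where they belong to the long or the short chromosome set of this allotetraploid frog, so that gsc.L and gsc.S are homeologous copies of goosecoid. The value of a gene was the mean log2 signal over its probe sets that passed the filter, and 1293 genes had several probe sets. No genome build is named for the array, so no coordinates are given.

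With 1 array per explant no statistical test, standard error or p-value was possible, and every difference is a difference between arrays without a replicate check. The comparisons were the dorsal against the ventral marginal zone, the animal cap against the vegetal explant, the marginal zones against both poles, and each explant against the other 3. A probe set was counted above both poles when the lower marginal zone was 2-fold or more above the higher pole, and as enriched in an explant when it was 2-fold or more above the highest of the other 3. For 15 gene lists fixed before the data were examined, the median log2 difference of the measured members was set against 10000 random lists of the same size matched on deciles of mean level. Its percentile describes these arrays, and 45 such percentiles were computed. The lists were the organizer, ventral, pan-mesoderm, endoderm, ectoderm, neural ectoderm, germ plasm and vegetal maternal, BMP synexpression, FGF synexpression, nodal target, Wnt target, retinoic acid, oxidative phosphorylation, ribosomal protein and cell cycle lists. They overlap: among others, the ventral and BMP lists shared 26 genes, the endoderm and nodal target lists 17, and the organizer and nodal target lists 14. The endoderm list shared 5 genes with the pan-mesoderm list and 4 with the organizer list. For list shifts in the third comparison, the difference was the mean of both marginal zones minus the mean of both poles.

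The genes named in the text followed a rule written before the data were examined. It took the 10 genes with the largest difference each way for the first 2 comparisons, the 10 most enriched in the marginal zones and the 6 most enriched in each explant, all above the floor on the sides compared. It also took up to 5 genes per side given as bounds, the 3 members of each list with the largest difference, and goosecoid, chordin, ventx1, ventx2, sizzled, brachyury, sox17, mixer, foxi1 and vegt as checks of the labels. Where a gene outside that rule is named, the text says so.

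Measures of error came from inside the arrays. These were the SD of the difference between probe sets of the same gene, the robust SD of the difference between the marginal zones by level of signal, 18 hybridisation control probe sets (bacterial and phage transcripts added in known amounts), and the ratios of 3' to 5' probe sets of GAPDH and actin. The procedure was tested on simulated arrays with 200 changed probe sets and noise taken from the spread between the marginal zones. At the deposited scaling it recovered 100% of 4-fold and 7% of 1.5-fold vegetal changes in the comparison of cap and vegetal explant (100 probe sets of each size, 8135 probe sets tested).

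Alternatives were median centring, quantile normalisation and cyclic loess of the arrays, floors at the 10th and 40th percentile, no filter, a filter at the 75th percentile, a 4-fold rule, the probe set with the highest mean level for each gene, and leaving out the 1433 probe sets whose name marks possible cross-hybridisation. Scaling to the hybridisation controls was added after their signals had been seen. Quantile and loess normalisation used limma 3.58.1 in R 4.3.3, and all else used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.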

Results

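RNA abundance was profiled in 4 explants of the stage 10 Xenopus laevis gastrula, with 1 array each for the animal cap, the dorsal marginal zone, the vegetal explant and the ventral marginal zone. The submitters' stated purpose was a regional expression profile from which expression patterns can be predicted by comparing explants. Between 7594 probe sets (animal cap) and 8020 (vegetal explant) had a signal at or above the filter of 147. No explant was replicated, so each value below is a single measurement in scaled intensity units.

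Regional marker genes gave a first check of the explant labels. Goosecoid, a homeobox gene of the Spemann organizer, had a gsc.S signal of 2662 in the dorsal marginal zone and 192 in the ventral one, with 51.3 in the animal cap and 2594 in the vegetal explant. The gsc.L probe sets reached 1018 and 3770 dorsally. Chordin, a secreted BMP antagonist made by the organizer, had chrd.1.S probe set signals of 855 and 3523 dorsally and lay at the floor ventrally. Sizzled, a ventral secreted inhibitor of chordin cleavage, ran the other way, with szl.S at 433 ventrally and 34.1 dorsally and szl.L at 186 ventrally and under the floor dorsally. Of the ventral homeobox genes, ventx2.1.L was 2165 ventrally and 1197 dorsally, ventx2.2.L 555 and 259, and ventx2.1.S 2375 and 1182. The ventx1.1.L probe sets were 440 and 268 ventrally against 75.6 and 237 dorsally. Brachyury (tbxt.S), a T-box gene of the mesodermal ring, was 676 in the dorsal and 886 in the ventral marginal zone, 146 in the vegetal explant and at the floor in the animal cap. A probe set for its relative tbxt.2.S stayed at or below 37.8 on all arrays. The endodermal genes sox17a.L, sox17a.S and mixer.S had vegetal signals of 1831, 1862 and 1630, and sox17b.1.S had 7246 and 6748 on its probe sets. In the animal cap these genes lay at or near the floor, while mixer.L was 483 in the vegetal explant. The T-box gene vegt.L was 7247 in the vegetal explant, 7351 and 6574 in the dorsal and ventral marginal zones and 349 in the animal cap, and vegt.S was 223, 184, 268 and at the floor. The ectodermal forkhead gene foxi4.2.L reached 2330 in the animal cap on its brighter probe set, 910 ventrally, 342 dorsally and 529 vegetally. In the same order, foxi4.2.S was 1231, 876, 336 and 317. Probe sets for foxi1.L (78.0 in the cap) and the dimmer probe set of foxi4.2.L stayed below the filter.

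**Figure D1:**
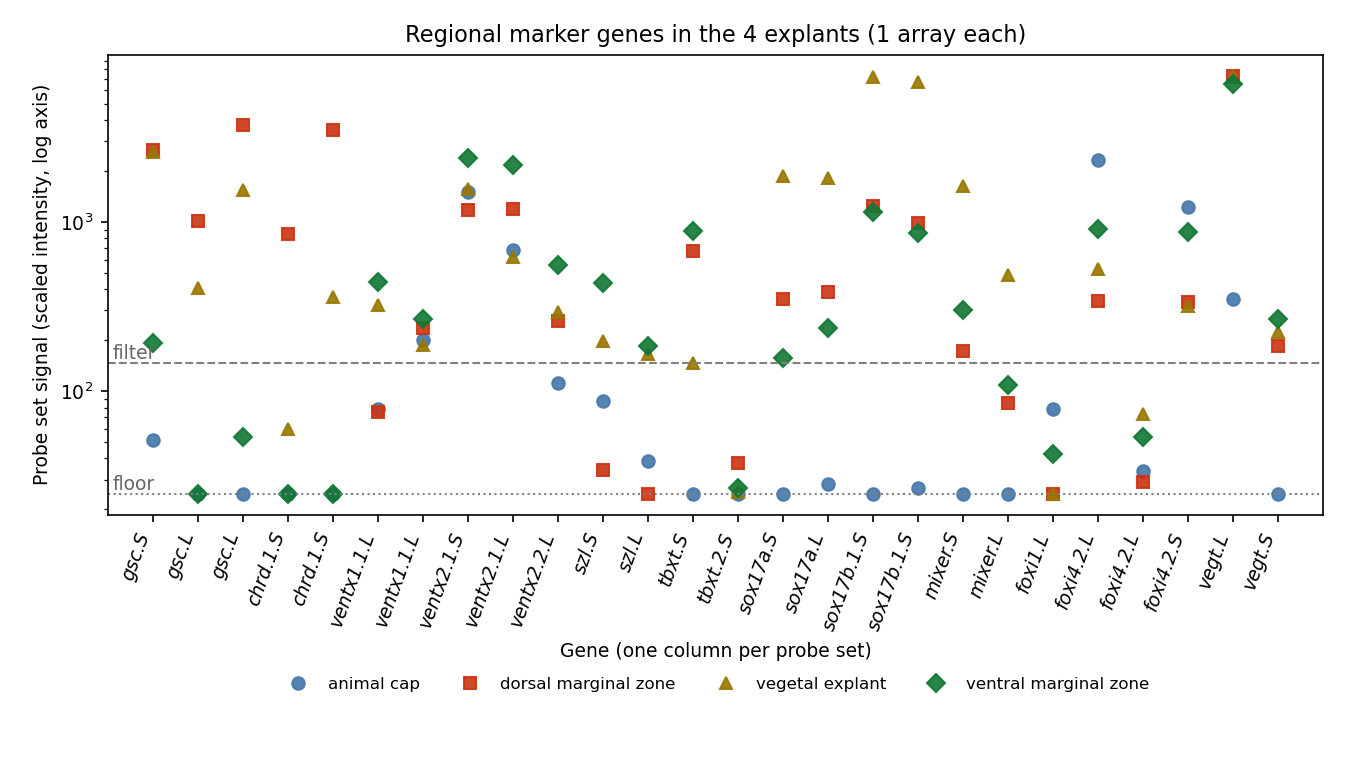
Signals (scaled intensity, log axis) of the probe sets of genes used to check the labels, with 1 point per explant and values under the floor drawn at the floor of 24.7. gsc and chrd.1 points lie highest in the dorsal marginal zone, szl points highest in the ventral marginal zone, and sox17 points highest in the vegetal explant.

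Across all probe sets that passed the filter, the marginal zones were the most similar pair of explants. Their Pearson correlation across probe sets was 0.958, their median absolute log2 difference was 0.17, and 2.56% of 8094 probe sets differed 2-fold or more. The animal cap differed 2-fold or more from the dorsal marginal zone at 5.86% and from the ventral at 4.68% of probe sets. The vegetal explant stood apart, with 17.7% against the dorsal marginal zone, 17.1% against the ventral marginal zone and 20.9% against the animal cap, where the correlation was lowest at 0.756. Probe sets are not independent replicates, so no p-value belongs to these correlations. The spread between the marginal zones depended on the level of the signal: its robust SD was 0.39 on the log2 scale over the 2698 dimmest probe sets by mean signal and 0.17 over the 2698 brightest.

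The dorsal and ventral marginal zones were compared to find genes that differ along the dorsal-ventral axis. Organizer genes were among the largest dorsal differences. The nodal-related ligand gene nodal3.1.L was 40.5-fold higher dorsally (1626 against 40.1), gsc.S 13.8-fold, the forkhead gene foxb1.S 8.52-fold and the Wnt antagonist gene frzb.L 7.92-fold. The brighter copy frzb.S differed far less, with 4852 dorsally and 3625 ventrally. Ventrally, ventx3.2.S was 17-fold higher (580 against 34), szl.S 12.7-fold, the homeobox gene evx1.L 11.8-fold and bambi.L, which encodes a pseudoreceptor that dampens BMP signalling, 11.1-fold over a dorsal signal of 29.5, just above the floor. In all, 112 probe sets were 2-fold or more higher dorsally and 95 ventrally, and 77 and 62 of them had 1 gene symbol.

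Among the 21 measured genes of the organizer list, 14 were 2-fold or more higher dorsally and none ventrally. The list median of 2.32 on the log2 scale lay above all random lists (100th percentile). Against the ventral floor, chrd.1.S was at least 70.3-fold, gsc.L at least 53.8-fold, the BMP-type ligand gene admp.S at least 24.8-fold and the Wnt antagonist gene dkk1.S at least 13.0-fold higher dorsally, and the head homeobox gene otx2.L at least 8.62-fold. Of 19 measured neural ectoderm genes, 9 were higher dorsally and none ventrally, with a median of 0.86 (100th percentile). They included otx2.L and the forkhead genes foxd4l1.1.S (7.1-fold) and foxd4l1.2.L (5.07-fold). Other large dorsal differences were those of the otx-related homeobox genes crx.S (16.6-fold) and crx.L (12.6-fold), hes7.1.L (7.2-fold), the myogenic gene myf5.L (6.82-fold) and lrig3.S (6.43-fold). The nodal target list had 10 of 26 genes higher dorsally and 1, wnt8a.L, higher ventrally (3.37-fold), with a median of 0.56 (100th percentile).

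The ventral list mirrored this, with 17 of 24 measured genes higher ventrally and none dorsally, and a median of -1.26 below all random lists. The BMP synexpression list, which shares most of these genes, had 17 of 25 higher ventrally and a median of -1.19 (below all random lists). Beyond those led by ventx3.2.S, szl.S and bambi.L, the BMP-responsive homeobox gene msx1.L was 5.22-fold higher ventrally, szl.L at least 7.53-fold and the mesogenin gene msgn1.L 6.08-fold. Epidermal genes were also higher in the ventral explant, where the keratin gene krt12.5.S was 5.86-fold and krt12.4.L 4.29-fold higher. The homeobox gene dlx3.S was 4.66-fold and the krüppel-like gene klf17.1.S 5.03-fold higher there. The ectoderm list accordingly split: 12 of 41 measured genes were higher ventrally and 6 dorsally (foxd4l1.1.S and zic4.L, at 5.19-fold, led the latter), with a median of -0.13 (percentile 0.36).

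The endoderm and retinoic acid lists lay towards the dorsal side. The endoderm list had 7 of 26 genes higher dorsally and none ventrally, among them frzb2.L (at least 7.01-fold), the secreted antagonist gene cer1.S (5.01-fold) and gata4.L (3.59-fold), and a median of 0.16 (percentile 99.57). It shares 4 genes with the organizer list, frzb2.L and cer1.S among them, so this is in part the organizer result again. In the retinoic acid list 1 of 8 genes, the retinaldehyde reductase gene dhrs3.L, was higher dorsally (2.61-fold), with a median of 0.37 (percentile 99.99). Of 18 pan-mesoderm genes, 2 (myf5.L and the growth factor gene fgf20.L, 2.21-fold) were higher dorsally and 1 (wnt8a.L) ventrally (median 0.13). The Wnt target list had 3 genes higher dorsally and 4 ventrally of 18, led by nodal3.1.L, myf5.L and msgn1.L, with a median of 0.05. In the FGF synexpression list 1 of 17, fgf20.L, was higher dorsally (median 0.11). No member of the germ plasm (17 genes), oxidative phosphorylation (55), ribosomal protein (72) or cell cycle (60) lists differed 2-fold.

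Simulated marginal zone arrays without a regional difference gave 59 probe sets past 2-fold and 12 past 4-fold of 8110, both directions together. Their noise was normal, with the robust spread of the observed dorsal minus ventral differences, real ones included. The simulation therefore gives no estimate of how many observed calls are noise. The observed numbers were 207 and 62 of 8094, and part of these counts can be noise. The hybridisation controls averaged 0.21 (log2) higher on the dorsal than on the ventral array, and with the arrays scaled to these controls 74 probe sets were higher dorsally and 185 ventrally, a dorsal share of 28.6% against 54.1% as deposited. The endoderm list's median then turned to -0.048, but this scaling lowers all dorsal minus ventral values by a like amount, random lists included.

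The animal cap and the vegetal explant were compared for the animal-vegetal axis, where differences were far more frequent. Vegetally, the germ plasm gene pgat.L was 270-fold higher (8243 against 30.6), the endodermal zinc finger gene gata6.L 246-fold, the germline RNA-binding gene dazl.L 117-fold, and cer1.S had 2740 against 24.7, a cap signal at the edge of the floor. In the animal cap, the keratin gene krt7.L was 80.0-fold higher (2931 against 36.6), the grainyhead-like epidermal genes grhl3.L and grhl1.L 42.2-fold and 30.9-fold, and the sodium pump subunit gene atp1b2.L 45.3-fold. Of 8614 probe sets, 787 were higher in the animal cap and 1011 in the vegetal explant, a cap share of 43.8%. With each array centred on its median the counts were 1098 and 756, a cap share of 59.2%, so which explant has more probe sets on its side is set by the scaling. The sizes of several of the largest folds are loose, because the lower signal lay just above the floor of 24.7. This holds for the cap signals of pgat.L, gata6.L, osr1.L, pcdh8.2.L and gata5.S (26.1 to 30.6) and for the vegetal signals of kctd15.L, rnf222.L and slc2a2.L (27.0 to 30.7).

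The measured endodermal and nodal target genes were almost uniformly vegetal. Of 31 measured endoderm genes, 30 were 2-fold or more higher vegetally and none in the cap, with a median of -4.61 below all random lists. They included gata6.L, cer1.S, the odd-skipped gene osr1.L (92.4-fold), gata5.S (85.2-fold), the TGF-beta ligand gene gdf1.S (77.5-fold) and sox17b.1.S (at least 273-fold). Of 27 nodal target genes, 26 were higher vegetally (median -5.01), and the nodal inhibitor gene dand5.S, named after its value was seen, was 6.46-fold higher in the cap. Organizer genes followed, with 20 of 22 measured members higher vegetally (median -4.09), among them frzb.S (at least 375-fold), frzb.L (at least 88.1-fold) and the protocadherin gene pcdh8.2.L (2243 against 26.1). The 2 organizer list members higher in the cap, named after their values were seen, were tdgf1.3.L (3.23-fold) and sfrp2.S (2.94-fold). Of 14 measured pan-mesoderm genes, 13 were higher vegetally (median -4.00), including wnt8a.L at least 115-fold and mixer.S at least 66.0-fold. The array held 36 genes of this list, and the filter kept only those with enough signal in the cap or the vegetal explant. It left out tbxt.S, aplnr.S, fgf20.L and myf5.L, with vegetal signals of 146, 42.5, 43.6 and 45.3. The count therefore does not speak for pan-mesoderm genes as a class. The same filter kept 31 of 38 endoderm, 27 of 38 nodal target and 22 of 32 organizer genes on the array. Among those left out was frzb2.L, at the floor in both explants. The counts of these lists too speak only for the measured members. The gene xenf.L was at least 200-fold higher vegetally. The medians of these 4 lists lay below all random lists.

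Germ plasm and vegetally localised maternal RNAs formed a further vegetal group. Of 22 measured genes of this list, 15 were higher vegetally and none in the cap, with a median of -3.20 below all random lists. Besides pgat.L and dazl.L, the RNA helicase gene ddx25.L was 80.8-fold higher, germes.L 64.9-fold and grip2.L at least 98.5-fold.

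Epidermal genes led the animal cap side. Of 40 measured ectoderm genes, 20 were higher in the cap and 7 vegetally, with a median of 1.03 (100th percentile). The keratin genes krt12.4.L and krt12.5.S were at least 98.1-fold and 49.4-fold higher, krt70.S, outside the list, at least 291-fold, dlx3.S at least 46.9-fold, and the ETS factor gene elf1.L at least 112-fold. The copy elf1.S, named after its value was seen, showed no cap excess, with 165 in the cap and 207 vegetally. Other large cap differences were those of rnf222.L (47.8-fold), ptafr.L (36-fold), the glucose transporter gene slc2a2.L (34.5-fold), raig4a (34.2-fold), kctd15.L (26.5-fold) and gprc5cl2.S (24.5-fold). Neural ectoderm genes split, with 6 higher in the cap and 5 vegetally of 18. The pan-neural SOX gene sox2.L was 6.71-fold and lhx5.S at least 12.3-fold higher in the cap, and otx2.L was 19.6-fold higher vegetally.

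The Wnt target and retinoic acid lists lay towards the vegetal side, with medians of -0.69 (percentile 0.03) and -0.94 (percentile 0.07). The ventral list had 8 of 23 genes higher vegetally and 1 in the cap (median -0.38, percentile 3.68), led by wnt8a.L, ventx3.2.S (46.7-fold) and cdx1.S (at least 16.3-fold). The BMP list had 7 vegetally and 4 in the cap of 25, led by ventx3.2.S, gata3.S (15.3-fold) and the tolloid-like gene tll1.S (9.07-fold), all vegetal, with a median of 0.02. In the FGF list 5 of 15 were higher vegetally and 2 in the cap, where the phosphatase gene dusp1.L was 5.64-fold higher while spry2.S was 4.90-fold and myc.S 3.89-fold higher vegetally (median -0.14). In the Wnt target list 5 of 14 were higher vegetally, with nodal3.1.L at least 62.1-fold, and 1, the cyclin gene ccnd1.L, in the cap (4.37-fold). The copy ccnd1.S, named after its value was seen, was 344 in the cap and 345 vegetally. In the retinoic acid list 4 of 8 were higher vegetally, among them the synthesis gene aldh1a2.L (at least 9.70-fold), the degradation gene cyp26a1.L (5.88-fold) and dhrs3.L (4.67-fold), and 1, rarg.S, in the cap (2.81-fold, named after its value was seen). In the cell cycle list 8 of 59 were higher in the cap and 4 vegetally: the cyclin gene ccne2.L was at least 8.26-fold higher in the cap, and the checkpoint kinase genes chek1.S and wee1.S were 5.81-fold and 4.63-fold higher vegetally. In the oxidative phosphorylation list 5 of 55 were higher vegetally, led by ndufb8.L (2.90-fold), cox5b.2.L (2.43-fold) and ndufs6.S (2.33-fold). None of 72 ribosomal protein genes differed 2-fold.

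Where a gene had several probe sets, the SD of the difference between them in this comparison was 0.77 on the log2 scale (95% bootstrap interval 0.68 to 0.86, 675 genes), against 1.60 for random pairs of probe sets. In 384 of 444 pairs with a member past 2-fold the other had the same sign. In 240 the other was also past 2-fold the same way, and in 9 both were past 2-fold in opposite directions. For the dorsal-ventral comparison the SD was 0.43 (631 genes), against 0.65 for random pairs, and 32 of 45 such pairs had the same sign. In only 12 of these 45 was the other probe set also past 2-fold the same way.

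**Figure D2:**
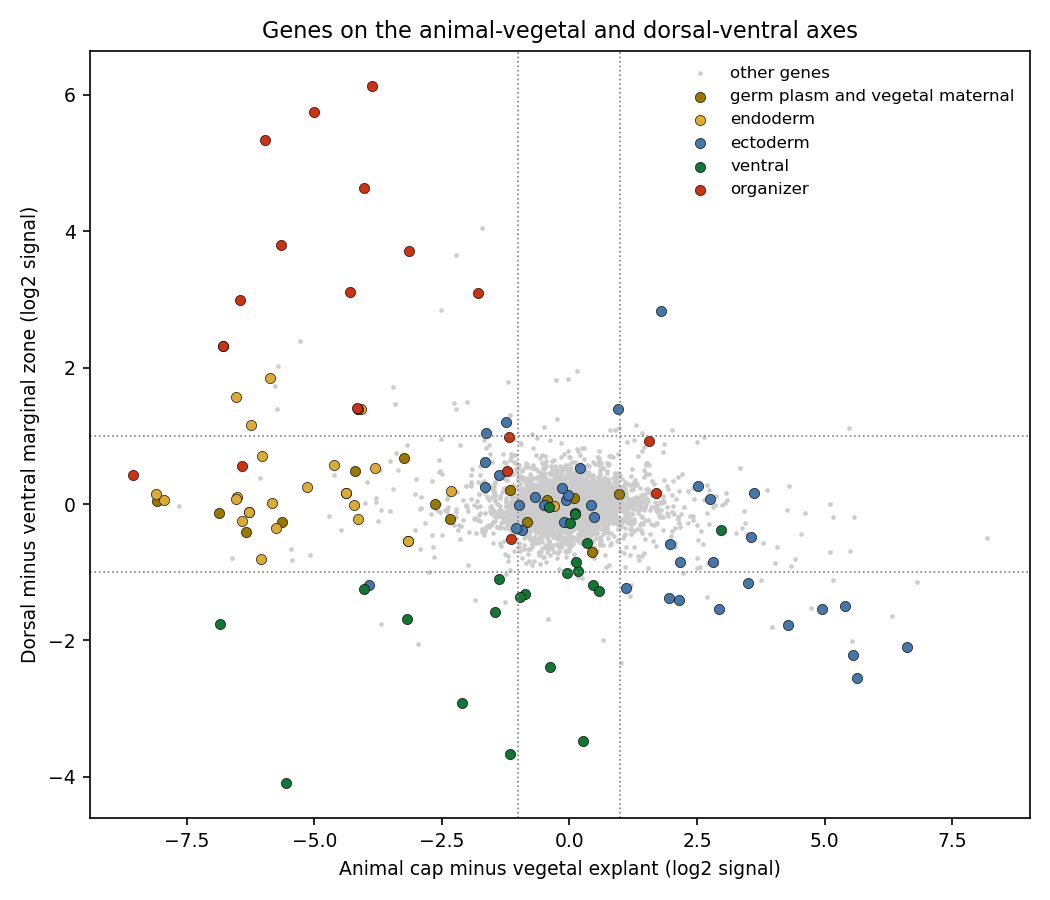
Each point is a gene measured in both comparisons, placed by the animal cap minus vegetal log2 difference (horizontal) and the dorsal minus ventral marginal zone log2 difference (vertical). Dotted lines mark 2-fold, and a gene in several lists has the colour of the list drawn last. Organizer genes lie to the upper left, ectoderm genes with large cap differences to the lower right, and endoderm and germ plasm genes to the left around 0 on the vertical axis.

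Both marginal zones were set against both poles to find genes of the mesodermal ring. Mesodermal genes led, with the apelin receptor gene aplnr.S 4.94-fold above the higher pole (313 and 210 against 33.0 and 42.5), tbxt.S 4.62-fold, fgf20.L 4.29-fold and fgf8.L 3.49-fold. Further genes were mettl7a.L (3.85-fold), the purine phosphorylase gene pnp.L (3.45-fold), hk1.L (3.30-fold), nat8.6.S (2.82-fold), the Notch-pathway gene hes7.2.L (2.71-fold) and glipr2.S (2.69-fold). In all, 34 of 8851 probe sets lay 2-fold or more above both poles and 2 below both. Of the latter, 1 belongs to the dehydrogenase gene rdh13.L (2.29-fold below the lower pole), named after its value was seen, and 1 has no symbol.

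The mean of the marginal zones minus that of the poles was 2-fold or more up in 16 of 19 pan-mesoderm genes and down in none, with a median of 1.90 (100th percentile). pcdh8.2.L was 18.1-fold, tbxt.S at least 12.9-fold and fgf20.L at least 8.46-fold higher on this measure. The nodal target list (17 of 30 higher, 1 lower, median 1.35, led by pcdh8.2.L, tbxt.S and gdf3.S), the organizer list (10 higher and 1 lower of 24, median 0.91) and the Wnt target list (8 of 18 higher, median 0.79, led by msgn1.L at least 7.74-fold and myf5.L at least 3.72-fold) lay at the 100th percentile. So did the FGF list (5 higher and 2 lower of 18, median 0.38) and the endoderm list (13 higher and 2 lower of 32, median 0.53). With the floor at the 40th percentile the endoderm median turned to -0.042. In the endoderm list gdf3.S was 8.31-fold and gata6.L 4.82-fold higher, and nodal5.2.L lay at the floor in every explant but the vegetal one (505). This measure averages both poles, so a low cap signal can raise it without a marginal excess over the vegetal explant. For gata6.L the vegetal signal was 7027, against 2204 dorsally and 2121 ventrally, with 28.6 in the cap. For gdf3.S it was 1888, against 2085 and 2064, with 33.0 in the cap. For pcdh8.2.L it was 2243, against 5307 and 3619, with 26.1 in the cap. The germ plasm list was lower in the marginal zones, with 9 of 22 genes lower and 3 higher and a median of -0.71 below all random lists, led by germes.L (at least 8.50-fold lower).

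The retinoic acid list had 2 higher and 0 lower of 8 genes and a median of 0.53 (percentile 99.95). The ventral list had 8 higher and 1 lower of 25, the BMP list 3 and 1 of 26, the ectoderm list 6 and 1 of 42 (foxd4l1.1.S 3.90-fold higher), the neural ectoderm list 3 and 0 of 19 (median 0.19, percentile 99.16) and the cell cycle list 2 and 1 of 60. No oxidative phosphorylation gene of 56 passed 2-fold. Of 72 ribosomal protein genes none passed 2-fold, yet the list median of 0.23 lay above all random lists (median 0.04), with rpl27a.L 1.78-fold and rps2.L 1.73-fold higher.

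**Figure D3:**
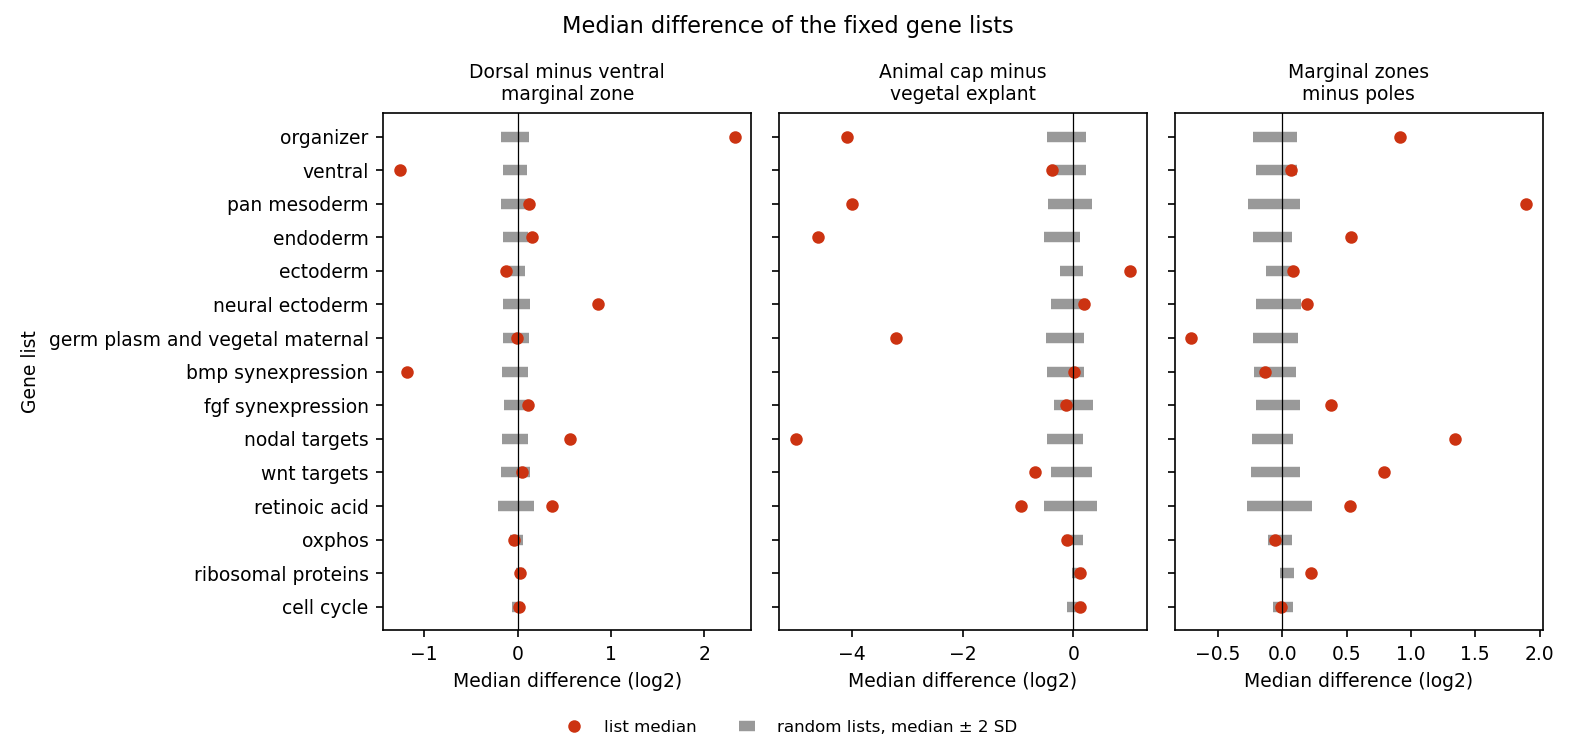
Median log2 difference of the measured members of each gene list (red points) in the 3 comparisons, with grey bars for the median of 10000 random lists of matched level ± 2 SD. The organizer list lies at 2.32 and the ventral list at -1.26 in the first panel, the endoderm list at -4.61 in the second and the pan-mesoderm list at 1.90 in the third.

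Each explant was last set against the other 3, which is the comparison that predicts a restricted pattern. The vegetal explant had 532 enriched probe sets, the animal cap 64, the dorsal marginal zone 28 and the ventral marginal zone 16. Germ plasm genes headed the vegetal group, with grip2.L 65.5-fold above the highest other explant, germes.L 54.6-fold, pgat.L 41.7-fold, ddx25.L 28.5-fold, dazl.L 23.8-fold and the germ cell gene dnd1.L 22.3-fold, and nodal5.2.L was at least 20.5-fold above. The animal cap group held the cement gland gene ag1.L (5.85-fold), the protease gene xepsin.L (5.1-fold), the cornifelin gene cnfn.1.L (4.39-fold), krt12.4.S (4.19-fold), vill.S (3.75-fold) and tmem45b.L (3.74-fold), and elapor2.L was at least 4.32-fold above.

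In the dorsal marginal zone chrd.1.S was 11.8-fold above the highest other explant, myf5.L 6.82-fold, pnp.L 5.92-fold, foxd4l1.1.S 5.56-fold, the Wnt antagonist gene sfrp1.L 4.97-fold, foxd4l1.2.L 4.0-fold and frzb2.L at least 7.01-fold. In the ventral marginal zone msgn1.L was 6.08-fold above, evx1.L 3.98-fold, lmo4.2.S 3.17-fold, msx1.L 2.40-fold, the C/EBP gene cebpa.L 2.24-fold and bmp7.1.L 2.21-fold. Among simulated probe sets without a change, 10 counted as vegetal-enriched, 11 as cap-, 12 as dorsal- and 6 as ventral-enriched. Part of the smaller observed groups can therefore be noise, but with the noise drawn as above these numbers do not say how much. The ventral count was 37 with the arrays scaled to the hybridisation controls and the animal cap count 97 with median centring.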

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

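The scaling to hybridisation controls was chosen after the data had been seen, and the other alternatives before. No paired analysis was possible because each explant had 1 array. The spread of a gene's value was taken as the SD between probe sets of a gene, divided by the square root of 2. Over the alternatives, 1230 of 1361 values of named genes moved by less than this spread. None reversed, but most of these genes were picked for large differences, so a reversal was unlikely from the start. Median centring and scaling to the hybridisation controls shift arrays against each other by at most 0.21 and 0.26 on the log2 scale. The SDs between probe sets, before that division, were 0.39 to 0.77, so these settings could move few values, and each moved 1. The floor at the 40th percentile accounted for 73 of the 131 that moved, since it lowers every bound. Of 450 list medians 302 stayed within the SD of their random lists, 146 moved and 2 reversed, and all 24 values of similarity between explants stayed within the SD of the hybridisation controls. Counted as reversed were the endoderm median of marginal zones minus poles and its dorsal minus ventral median. The former was -0.042 with the floor at the 40th percentile. That floor changes only the signals below it, so the positive median depended on such low signals. Which explants held them was not counted. The endoderm list's dorsal minus ventral median was -0.048 with scaling to the hybridisation controls, which lowers dorsal minus ventral values as a whole by the 0.21 between the controls. Among others, the pan-mesoderm, FGF and Wnt target medians, dorsal minus ventral, were 0.13, 0.11 and 0.05 as reported. A shift of 0.21 would turn them negative too, so the 2 counted as reversed do not cover every change of sign.

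The SD between probe sets of a gene, which serves as a measure of error, moved by more than its bootstrap error in each of the 3 alternatives run for it. Cap minus vegetal it was 0.77 as reported, 0.82 without a filter, 0.66 with the filter at the 75th percentile and 0.88 without probe sets marked for cross-hybridisation, and dorsal minus ventral 0.43, 0.51, 0.34 and 0.47. Counts of probe sets moved by over 1.5 times mainly where the rule itself was changed. The 4-fold rule left 37 dorsal, 25 ventral, 235 cap and 371 vegetal probe sets, 7 above and 0 below both poles, and 7 cap-, 11 dorsal-, 113 vegetal- and 3 ventral-enriched ones. The filter at the 75th percentile left 45, 45, 404 and 429, then 16 and 0, and 33, 16, 273 and 10 in the same order, with fewer probe sets tested. Without a filter, with dim probe sets added, 291 were dorsal, 262 ventral, 1693 vegetal and 11 below both poles, and 50 dorsal- and 35 ventral-enriched. The floor at the 40th percentile left 1 below both poles and median centring gave 97 cap-enriched ones. Scaling to the hybridisation controls gave 74 dorsal, 185 ventral and 37 ventral-enriched probe sets, since it raises the ventral array as a whole. The median of all probe sets, cap minus vegetal, was -0.10 as deposited and 0.11 with median centring, 0.02 with quantile normalisation and -0.01 with loess. The cap share of cap and vegetal calls was 43.8%, 59.2%, 50.4% and 48.5% under these 4 scalings. Signal over background limited the lower end, as 17.2% to 21.5% of probe sets per array lay at the floor, where only bounds can be had.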

Other observations

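The tests of carried or added tissue, of scaling and of RNA degradation were chosen after the results had been seen, as were the counts of low explants and the means of neighbours with pairs left out; the tests of ectoderm in the marginal zones, of homeologous copies and of neighbouring genes were set before.

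Genes low in a single explant add to the patterns above. These genes were named after their values were seen. In the vegetal explant 473 probe sets were 2-fold or more below the lowest of the other 3 explants, in the animal cap 192, in the dorsal marginal zone 17 and in the ventral marginal zone 9. The named genes farthest down in the animal cap included gata6.L, 74.2-fold below the lowest other explant, gdf3.S (57.2-fold) and frzb.S (at least 147-fold). Those in the vegetal explant included rnf222.L (22.5-fold below), ptafr.L (18.2-fold) and krt70.S (at least 119-fold). In the dorsal marginal zone bambi.L lay 4.44-fold, klf17.L 3.97-fold, klf17.1.S 2.95-fold and szl.S 2.58-fold below the lowest other explant. The ventral group was led by crx.S (2.37-fold), the Iroquois gene irx2.L (2.28-fold) and cebpd.S (2.22-fold).

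Organizer genes that were higher dorsally than ventrally mostly also had high signals in the vegetal explant: the median of 14 such genes was 69.3% of the dorsal signal, and frzb.L, cer1.S and a2m.S (named after its value was seen) exceeded 100%, while frzb2.L lay at the vegetal floor. Carry-over of whole dorsal marginal zone tissue into the vegetal explant would bring every abundant dorsal transcript in a like share, but pnp.L stood at 2.28%, foxd4l1.1.S at 5.15% and chrd.1.S at 8.44% of their dorsal signals of 1865, 2480 and 1735. The other abundant dorsal genes, crx.S and crx.L, stood at 47.2% and 49.8%. The 13 organizer genes above the vegetal floor lay more than 2-fold above the lowest of these percentages, and 12 of them more than 2-fold above chrd.1.S. The tables therefore argue against carried whole tissue as the main source. Carry-over from only the vegetal edge of the dorsal marginal zone, or expression in the dorsal vegetal cells themselves, may each give this pattern and was not tested.

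Epidermal genes were higher in the ventral than in the dorsal marginal zone, with a median log2 difference of -1.51 over 12 ectoderm list genes outside the neural list that were 4-fold or more higher in the cap than vegetally. Added animal tissue would bring a like percent of the cap signal for every cap-high gene; where the dorsal signal is at most 1/2 of the cap signal, the ventral signal needs a median of 42.7% (quartiles 30.8 to 53.6) over 11 epidermal genes and 27.4% (15.3 to 37.8) over 33 cap-high genes outside the ectoderm and BMP lists, and where it is at most 1/4, 42.7% (35.7 to 49.0) over 7 and 28.2% (23 to 36.4) over 6. The median of the other genes lies below the epidermal quartiles, and at 42.7% 7 of the 33 fell short of the needed signal by over 2 robust SDs and 1 exceeded it, against 1 short in the median random set of matched level: MGC68910 needed -43.3%, its ventral signal lying below the dorsal one, raig4a 0.28%, rassf7.L 0.89%, gnb3.L 2.99%, dand5.S 3.64%, gprc5cl2.S 8.85% and cnfn.1.L 15.3% (genes named after their values were seen). The quartile ranges overlap, however, and at 30.2%, the low end of the bootstrap 95% interval of the epidermal median, 4 fell short, which is still within the central 95% of the random sets (up to 4), so added tissue, as the whole or a part, and a regional difference cannot be told apart. Several criteria were tried with the percentages known, and a rule on the medians alone would have excluded added tissue. The 33 other genes include keratin genes outside the lists, krt7.L (32.1%), krt70.S (28.9%) and krt70.L (22.6%). The contrast is therefore not strictly one of epidermal against non-epidermal genes. A difference between dorsal and ventral ectoderm carried in both explants stays open and was not tested.

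The vegetal explant had 8.31 times as many enriched probe sets as the animal cap (532 against 64). The tables argue against scaling as the whole cause, since the ratio was 4.15 to 6.60 under median centring, quantile normalisation and loess. Ectoderm carried in the marginal zone explants cannot be told apart from expression across the equator: the planned test, a gap of 44.5 percentage points between the shares of cap-high and vegetal-high probe sets with a marginal zone within 2-fold, is void, since the counts of enriched probe sets alone fix it. Greater RNA degradation in the vegetal explant cannot be told apart from the region, because 1 of 2 controls stood out there: the GAPDH 3' to 5' ratio was 5.85 against 3.99 to 4.45 elsewhere, while the actin ratio was 0.711 against 0.679 to 0.705.

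A first hypothesis was that homeologous .L and .S copies differ in regional pattern by more than probe set noise alone. Over 576 pairs the SD of the difference between copies, cap minus vegetal, was 0.96 (95% bootstrap interval 0.83 to 1.09), against 0.77 (0.68 to 0.86) between probe sets of the same gene. The SD between copies was the larger, but the intervals overlap, and by the rule set before, divergence and noise were then not told apart. Overlap of intervals is not a test of the difference, and no such test was run. A copy's value is also a mean over its probe sets, whereas the other SD is between single probe sets. The SD between probe sets was 0.88 without those whose name marks possible cross-hybridisation, and hybridisation of one copy's RNA to the other copy's probes, which would shrink the difference between copies, was not checked. Of 150 pairs with a copy past 2-fold, 43 had both copies past it the same way and 3 had them past it in opposite directions. In the latter, pkp3, slc48a1 and tmpo, all named after their values were seen, pkp3.L was higher vegetally (1133 against 541) and pkp3.S in the cap (382 against 165).

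A second hypothesis was clustering of regional genes along chromosomes. Over 733 adjacent pairs of measured genes with different name stems, the mean product of standardised cap minus vegetal differences was 0.119, outside the central 95% of 1000 shuffles of gene positions (-0.07 to 0.08). Of 20 pairs with both genes past 2-fold, 15 went the same way. The 3 highest products, seen after the test, join mix1, mixer and bix1.1, related homeobox genes that share vegetal expression. Without these 3 pairs the mean was 0.039, within the central 95% of shuffles treated alike (-0.074 to 0.075), and without the 5 highest and 5 lowest products it was 0.046 (-0.051 to 0.051), so clustering beyond this family is not shown.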
